A study of Homo sapiens with 34 samples.

How the data were processed

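The material was LNCaP, an established human prostate cancer cell line whose growth depends on androgen. Androgen-dependent cells (AD) grew in standard medium, and an androgen-independent derivative (AI) was kept in medium with serum stripped of steroids by charcoal. The series held 34 samples. They comprised 8 libraries of RNA immunoprecipitation (RIP) after ultraviolet crosslinking, with an antibody to EZH2 or control IgG, and 12 RNA-seq libraries. The other samples were 7 chromatin immunoprecipitation (ChIP) libraries for EZH2 or the histone mark H3K27me3 and their 7 inputs, which were not analysed separately here. EZH2 is the enzyme of Polycomb repressive complex 2 (PRC2) that places H3K27me3. RNA-seq covered untreated cells and cells collected 24 h after transfection with siRNA against EZH2 (siEZH2) or a mock siRNA. Groups and replicate numbers were taken from the sample titles. Every group held 2 samples except the EZH2 ChIP of AI cells and its input, which held 1 each. The treatment protocol in the labels speaks of transfecting LNCaP/abl, an androgen-independent line, whereas libraries titled AD also carry siRNA names. The titles were followed, so the AD mock and AD siEZH2 values hold only if those titles are right. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

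The authors deposited RPKM values (reads scaled to gene length and library size) with 2 decimals for RNA-seq and RIP, and the submitters' processing notes name cutadapt, TopHat2 and edgeR for RNA-seq, TopHat2 and edgeR for RIP, and the build GRCh38, without versions or roles. The annotation release, the counting tool and its use of strand are not given in the sources used here. For RNA-seq 28071 genes were listed and for RIP 25035, of which 22349 were also in the RNA table. Ensembl identifiers were matched to a gene name table, which gave 22627 RNA and 20331 RIP identifiers a symbol and lacked 540 and 529. Among the RNA-seq symbols 27 had turned into dates, so identifiers were used throughout. The deposited peak lists give a score per peak, which is the authors' own value and was at least 50 in every list, and it was used only to rank peaks within a list. Peak names have the form that MACS writes, with no version or settings given, and the submitters' processing notes name cutadapt and Bowtie2. Each list came from 1 ChIP sample against its own input.

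RPKM carries no read totals. Depth was therefore estimated from the steps between low values, with a tolerance of 1.0%, since the value of 1 read depends on depth and gene length. The RNA-seq estimates rest on 9 to 41 values a library and are approximate. In the RIP table the shortest gene length that gave whole reads was taken, which was found for 13624 of 13667 genes (99.7%). As a check, the recovered gene lengths were applied to 5724 RNA-seq values, of which 92.7% came out whole against 12.3% by chance, and 92.7% of 300 simulated lengths were recovered within 2%. Both checks concern low values. In a simulation by level, 94% of lengths were recovered at 5 RPKM, 79.5% at 10, 35.5% at 30 and 6.5% at 100, and nearly all failures were too short: MALAT1 came out at 72 nucleotides. The 3946 genes with a mean of 5 RPKM or more therefore have no dependable length or reads, and the tests that use them were repeated on the other 9678 genes.

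The main test was limma-trend on log2(RPKM + 0.5), with a coefficient per group over all 12 RNA-seq or all 8 RIP libraries and Benjamini-Hochberg adjustment at 0.05. Genes needed 0.5 RPKM or more in at least 2 libraries, which left 14227 RNA-seq and 13667 RIP genes. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. A coefficient for the difference of differences tested whether an effect differed between AD and AI or between experiments. The design had allowed for counts; since the files hold RPKM, edgeR and DESeq2 were not run.

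There were 22 gene lists fixed before the data were examined. They covered androgen-induced and androgen-repressed genes, the G1/S and G2/M phases, PRC2, PRC1, enzymes of H3K27 and H3K36 methylation, splicing factors, neuroendocrine, luminal, mesenchymal, basal, and blood or stromal markers. The others were Polycomb developmental targets, genes reported as silenced by EZH2 in prostate, cholesterol synthesis, interferon response, amino acid and endoplasmic reticulum stress, hypoxia and glycolysis, abundant noncoding RNAs, ribosomal proteins and mitochondrially encoded genes. Each list with at least 3 tested genes was compared with all other genes by camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list.

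Named genes followed a rule, also fixed before the data were examined. EZH2 came first. Next came, per comparison, the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 1 RPKM and groups that did not overlap. Up to 4 members of each list followed, taken by smallest adjusted p where at least 3 were called, otherwise at most 2. KLK3, TMPRSS2, FKBP5, UBE2C, CDC20 and CDK1 were always given for AI against AD. For H3K27me3 the 3 widest regions and the 5 largest expression changes of each class were named. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

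Peak lists were compared by the Jaccard index in base pairs and by overlap of at least 1 bp, with functions checked against bedtools on simulated lists. EZH2 peaks were shuffled 1000 times within chromosomes to give a chance level. The planned promoter tests were not run because transcription start sites were not at hand; spans of 12904 of the 14227 genes (90.7%) from a RefSeq table of GRCh38, with 2000 bp either side, stood in for them. A first definition (at least 50% of the span covered in a cell type, under 10% in the other) gave 1 gene with the mark lost in AI, 6 with it gained and 7 with it kept. It was replaced, after the class sizes and before any expression value of the classes was seen, by a peak in both lists of a cell type and in neither list of the other. Kept genes had a peak in all lists. Means were compared by two-sided permutation tests with 100000 resamples across genes, which are not independent replicates. For RIP the planned set of transcripts at an adjusted p under 0.05 was empty. The 500 transcripts with the largest enrichment, a set that the design does not name, were used instead, matched on 10 expression deciles.

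The script was tested on simulated data drawn from these libraries. Of 100 genes changed by 1 on the log2 scale, the test recovered 72% for untreated AI against AD, 66% after mock transfection, 75% for siEZH2 in AD and 63% for siEZH2 in AI, and at a change of 2 it recovered 95%, 97%, 93% and 94%. For the difference of siEZH2 effects recovery was 41% and 88%. In the RIP design, fitted without the replicate block, it recovered 0% at either size. Voom on the recovered reads found 42 of 200 genes (21%) changed by 2 in AD, so the absence of calls there says little.

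The alternatives tried were pseudocounts of 0.1 and 1, no filter or a mean of at least 2 RPKM, quantile normalization, TMM scaling, the replicate number as a block, a fit of the compared groups alone, a log2 change of at least 1, each library left out in turn, stricter peak scores, equal list lengths and stricter overlap. Further alternatives were chosen after seeing the data: leaving out mitochondrially encoded genes, limma voom on the recovered RIP reads of all genes or of those under a mean of 5 RPKM, other flanks and coverage for gene spans, and the contrasts between mock and untreated libraries. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, limma 3.58.1, bedtools 2.31.1 and matplotlib 3.10.9.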

Results

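RNA-seq was collected from AD and AI cells in 3 states with 2 libraries each: untreated, 24 h after mock siRNA, and 24 h after siEZH2. RIP was collected with EZH2 antibody and with IgG in AD and AI cells, again with 2 libraries each. Peak lists covered H3K27me3 in 2 AD and 2 AI samples and EZH2 in 2 AD samples and 1 AI sample. The estimated depth of untreated RNA-seq was 17.4 and 57.8 M reads (M, mega) in AD and 18.5 and 51 M in AI. Mock libraries had 9.57 and 12 M (AD) and 8.94 and 12.7 M (AI), and siEZH2 libraries 9.47 and 12 M (AD) and 7.78 and 7.54 M (AI). EZH2 RIP had 8.16 and 7.04 M reads in AD and 7.84 and 4.61 M in AI. IgG was far shallower, with 0.372 and 1.85 M in AD and 0.613 and 0.0814 M in AI. A first estimate from short genes alone gave 1.54 M for EZH2 RIP replicate 2 of AI and 0.307 M for IgG replicate 1 of AI. The depths of these libraries are therefore uncertain. Replicates correlated at 0.973 to 0.99 in RNA-seq and at 0.885 (AD) and 0.861 (AI) for EZH2 RIP, but at 0.66 (AD) and 0.557 (AI) for IgG. Mitochondrially encoded genes made up 18.01% and 32.06% of the summed RPKM in untreated AD and 19.24% and 32.98% in untreated AI, against 2.09% to 4.06% in every transfected library.

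EZH2 (ENSG00000106462.10, chromosome 7), the target of the siRNA, was higher in untreated AI cells (11.4 ± 1.77 RPKM, SD, n = 2) than in untreated AD cells (6.08 ± 1.22), a log2 change of 0.86 (SE 0.183, limma adjusted p = 0.00607). After mock transfection the order was the opposite, with 6.26 ± 1.15 RPKM in AI and 11.7 ± 1.08 in AD, and EZH2 fell by 0.86 on the log2 scale (adjusted p = 0.00286). With quantile normalization that fall was -0.35 (adjusted p = 0.155) and with TMM scaling -0.40 (adjusted p = 0.103), so the call after mock transfection depended on the scaling. The untreated rise had adjusted p values from 0.00447 to 0.0636 over all alternatives, the highest in a fit of the untreated libraries alone. In AD cells siEZH2 left EZH2 at 11.1 ± 0.559 RPKM (log2 change -0.07, adjusted p = 1). In AI cells EZH2 was 3.97 ± 0.516 RPKM after siEZH2, a log2 change of -0.59 against mock that did not pass the test (adjusted p = 0.126). In AD the libraries labelled siEZH2 therefore carry no knockdown that the test could detect. In AI the fall did not pass after adjustment over 14227 genes, in a design that recovered 63% of simulated changes of 1. EZH2 was named in advance as the target, and for such a gene an adjustment over all genes is strict. Its log2 change in AI lay between -0.77 and -0.42 over 14 settings, which share the same libraries. A knockdown in AI is thus neither shown nor excluded by this test. The effects of siEZH2 did not differ detectably between AI and AD for this gene (difference -0.52, adjusted p = 0.767).

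**Figure D1:**
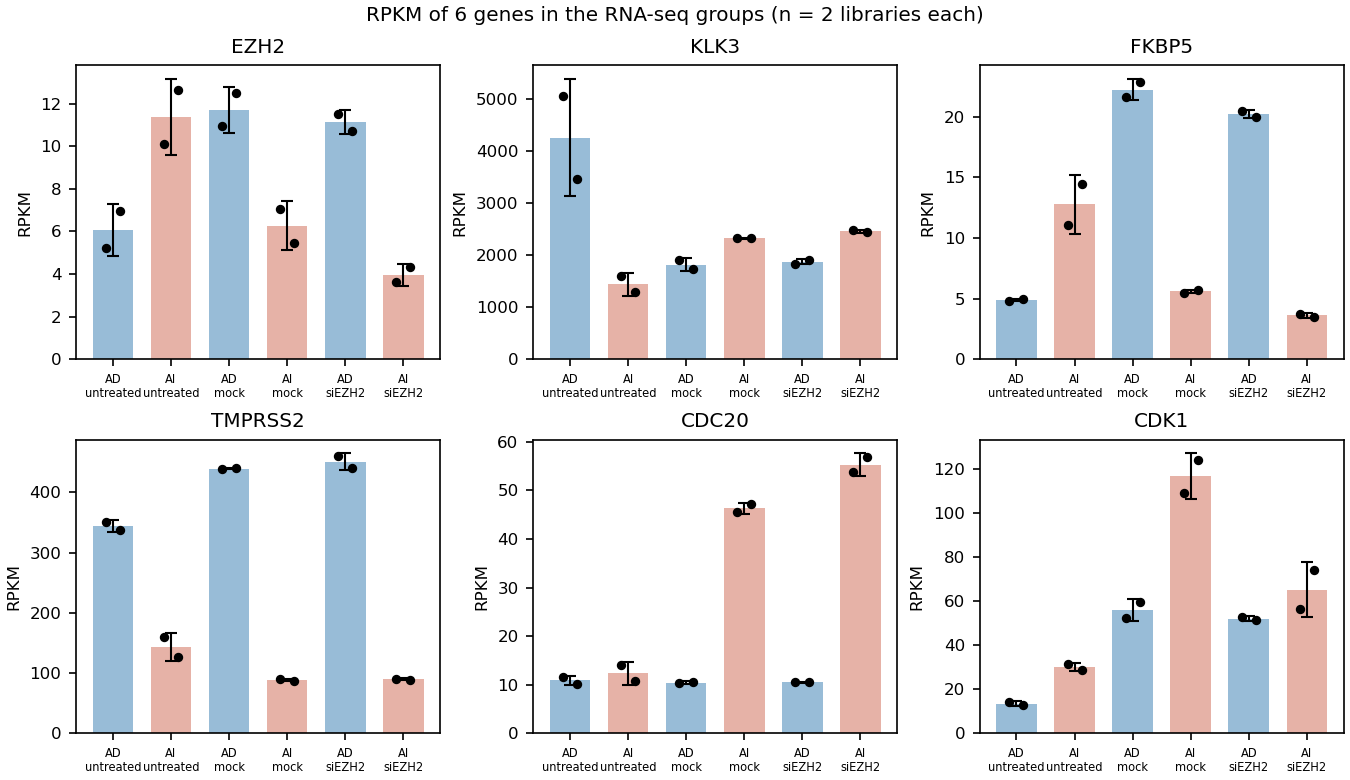
RPKM of EZH2, KLK3, FKBP5, TMPRSS2, CDC20 and CDK1 (y axis, linear, from 0) in the 6 RNA-seq groups; bars are means, points the 2 libraries, error bars the SD. EZH2 and FKBP5 are higher in AI than in AD when untreated and lower in AI in the transfected groups, which for EZH2 after mock transfection did not pass the test with quantile normalization or TMM scaling.

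The first comparison asked how untreated AI cells differ from untreated AD cells. The largest rises in AI were TMEM45B (log2 change 5.71), PTGR1, an enzyme of prostaglandin and leukotriene breakdown (5.59), BASP1 (5.26), BANK1 (4.59), the neuronal microtubule protein MAP2 (3.98), TCEAL9 (3.93) and TNFRSF14 (3.51), as well as HTATIP2, which was listed at 0 in both AD libraries and at 7.43 ± 1.33 RPKM in AI. PTGR1 went from 0.145 ± 0.106 RPKM in AD to 30.9 ± 8.26 in AI (SD, n = 2). The largest falls were NDUFA4L2, a hypoxia-induced mitochondrial protein (-7.57, from 465.8 ± 23.6 to 1.96 ± 0.283 RPKM), VEGFB (-6.14), VSTM2L (-4.97), the odorant receptor OR51E1 (-4.87), the lactate exporter SLC16A3 (-4.67), the sodium channel subunit SCNN1G (-4.57) and midkine, MDK (-4.56). BCAP31P1 (-4.89) is a pseudogene whose reads could belong to its parent gene, so its value is uncertain. Among androgen target genes, KLK3 (prostate-specific antigen) fell by 1.55 on the log2 scale (4262 ± 1120 to 1443 ± 222 RPKM) and TMPRSS2 by 1.26, while FKBP5 rose by 1.29 (4.88 ± 0.0636 to 12.8 ± 2.42 RPKM).

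Hypoxia and glycolysis genes fell together in untreated AI: 14 of 14 tested members fell, with the same count adjusted over the list alone. Among them were the phosphofructokinase regulator PFKFB4 (-4.30), carbonic anhydrase CA9 (-3.67), the glucose transporter SLC2A1 (-2.49) and ANKRD37 (-1.86). The camera adjusted p was 1.57e-17 at the preset correlation, and adjusted p = 0.0436 with an estimated correlation. Of 7 mesenchymal markers, 5 fell and 0 rose (also 5 adjusted over the list alone), among them FN1 (-2.76), VIM (-2.84), COL1A1 (-0.97) and SNAI1 (-1.21), with adjusted p = 0.00159 (adjusted p = 0.0989 with an estimated correlation).

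Several lists moved upward in untreated AI. Of 19 cholesterol synthesis genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with ACACA, the carboxylase that starts fatty acid synthesis, at 1.20 and SC5D at 1.14, while the desaturase SCD fell by 1.35. Of 48 splicing factors, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with SRSF7 at 1.05, SRSF3 at 0.80, DDX5 at 0.74 and TRA2A at 0.71. Of 20 G1/S and replication genes, 10 rose and 1 fell (11 and 1 over the list alone), with PCNA at 1.04 and MCM5 at 1.00. Of 22 G2/M genes, 10 rose and 1 fell (10 and 1 over the list alone), with CDK1 at 1.13 and CCNA2 at 1.17, while UBE2C (-0.32, adjusted p = 0.203; -0.59, adjusted p = 0.023 without AD replicate 2, and -0.53, adjusted p = 0.0456 with quantile normalization) and CDC20 (0.17, adjusted p = 0.359) did not pass. Of 15 stress genes, 10 rose and 1 fell (10 and 1 over the list alone), with the serine synthesis enzyme PSAT1 at 1.83, ATF3 at 0.99 and XBP1 at 0.77, while DDIT4 fell by 1.48. At the preset correlation the camera adjusted p was 0.00667 for cholesterol synthesis, 0.0106 for splicing, 0.0161 for G1/S, 0.0205 for G2/M and 0.0163 for stress. With an estimated correlation these calls were lost (adjusted p = 0.124, 0.116, 0.124, 0.124 and 0.123), and the G2/M call was also lost with quantile normalization (adjusted p = 0.0999) and TMM scaling (adjusted p = 0.0578).

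The other lists did not pass camera in untreated cells. Of 24 androgen-induced genes, 11 rose and 6 fell (adjusted p = 0.581); NDRG1 fell by 4.46 and PMEPA1 rose by 0.95. Of 5 androgen-repressed genes, 2 rose and 3 fell (adjusted p = 0.205), with CAMK2N1 at 1.38, BCHE at -2.41, UGT2B17 at -2.85 and UGT2B15 at -2.65. Of 11 PRC2 genes, 3 rose and 1 fell (adjusted p = 0.783): SUZ12, a core subunit, rose by 0.80 and PHF1 fell by 0.67. PRC1 had 5 rises and 6 falls of 17 (adjusted p = 0.347), with CBX6 at 1.11. The H3K27 and H3K36 enzymes had 0 rises and 3 falls of 12 (adjusted p = 0.112; 0.0406 with quantile normalization, downward), with the demethylases KDM4B at -1.09, KDM2B at -1.07 and KDM6B at -0.78. The interferon list had 8 rises and 2 falls of 12 (adjusted p = 0.0745), with OAS1 at 1.27, RIGI at 1.18 and IFI6 at -0.90; it passed with quantile normalization (adjusted p = 0.0406) and TMM scaling (adjusted p = 0.0397). Luminal markers had 3 rises and 3 falls of 14 (adjusted p = 0.783), with AMACR at 2.11 and KRT19 at -2.34. Ribosomal proteins had 2 rises and 3 falls of 34 (adjusted p = 0.0721; 0.0437 with TMM scaling, downward). Mitochondrially encoded genes had 1 rise and 0 falls of 15 (adjusted p = 0.571). Noncoding RNAs had 2 rises and 2 falls of 15 (adjusted p = 0.445), with MALAT1 at -1.20 and NEAT1 at -1.10. EZH2-silenced genes had 4 rises and 3 falls of 10 (adjusted p = 0.783), with BMPR1B at 1.66 and CDKN1C at -1.98, and Polycomb developmental genes 2 and 2 of 8 (adjusted p = 0.97). Markers of other cells were few: 4 basal genes were tested and 2 fell (KRT14 at -1.48, ITGB4 at -0.89; adjusted p = 0.108), 3 blood or stromal genes and 1 fell (VWF at -2.04; adjusted p = 0.192), and 2 neuroendocrine genes, both of which fell (ENO2 at -2.26, SYP at -0.89; without AD replicate 1 SYP was at -0.60 with adjusted p = 0.0528). Adjusted over the list alone, the rises and falls were 13 and 6 for androgen-induced genes, 9 and 2 for interferon, 4 and 4 for luminal, 6 and 6 for PRC1, 1 and 3 for ribosomal proteins, 0 and 2 for noncoding RNAs and 3 and 2 for Polycomb developmental genes, and equal to those given for the other lists.

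In total 4922 of 14227 genes were called between untreated AI and AD, 3158 higher and 1764 lower, and the median gene changed by 0.13. The split depended on the scaling, with 2336 higher and 2291 lower after quantile normalization and 2080 higher and 2416 lower with TMM scaling. A fit of the 4 untreated libraries alone called 1758 genes and ended the calls of EZH2, CCNA2, DDX5, TRA2A, SUZ12, PHF1, KDM6B, IFI6, XBP1, ITGB4, SYP and MALAT1, with adjusted p values between 0.0524 (MALAT1) and 0.0766 (SUZ12).

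The mock-transfected cells put the same question to another set of libraries. PTGR1 (log2 change 5.98), HTATIP2 (5.31, from 0.075 ± 0.106 to 22.3 ± 2.57 RPKM) and TMEM45B (4.72) were again among the largest rises in AI, followed by CYB5R2 (4.00), ANKRD37 (4.00) and the transcriptional inhibitors ID2 (3.71) and ID3 (3.67). SNORA18, listed at 0 in both AD libraries and at 8.76 ± 3.17 RPKM in AI, is a small RNA inside a host gene and its value is uncertain. The largest falls were DIO3, which inactivates thyroid hormone (-8.28, from 226.8 ± 21.3 to 0.235 ± 0.12 RPKM, SD, n = 2), lipocalin LCN2 (-7.16), the interferon-induced OASL (-6.27), butyrylcholinesterase BCHE (-6.13), CHST2 (-5.76), IFITM2 (-5.41), SLC16A3 (-5.40) and TNNT1 (-5.24). Among androgen target genes TMPRSS2 fell by 2.30 and FKBP5 by 1.90, while KLK3 was 1819 ± 132 RPKM in AD and 2321 ± 1.12 in AI (0.35, adjusted p = 0.129). With TMM scaling KLK3 was at 0.84 (adjusted p = 0.00367) and with quantile normalization at -0.59, and its adjusted p ranged from 0.00363 to 0.373 over the alternatives.

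Interferon genes fell together in mock-transfected AI cells: 12 of 12 fell, also 12 adjusted over the list alone, with BST2 at -4.21, OAS1 at -3.58, IFI6 at -3.09 and RIGI at -2.78 (camera adjusted p = 0.000187; adjusted p = 0.0373 with an estimated correlation). Of 19 cholesterol synthesis genes, 15 rose and 1 fell (16 and 1 over the list alone), with the sterol sensor INSIG1 at 33.3 ± 4.91 RPKM in AD and 378.8 ± 21.4 in AI, FDFT1 at 2.62 and SCD at 2.39 (adjusted p = 3.56e-14; adjusted p = 0.0078 with an estimated correlation). Of 15 stress genes, 11 rose and 1 fell (11 and 1 over the list alone), with ATF3 at 2.70, CHAC1 at 2.57, DDIT3 at 1.70 and TRIB3 at 1.54 (adjusted p = 7.16e-10; adjusted p = 0.0078 with an estimated correlation).

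Ribosomal protein genes rose in 33 of 34 members, 33 also over the list alone, with RPS6 at 1.52 and RPL5 at 1.30 (camera adjusted p = 1.35e-18). With an estimated correlation that call was lost (adjusted p = 0.169). Of 15 noncoding RNAs, 10 rose and 2 fell, with SNHG1 at 2.24, PVT1 at 1.81 and MALAT1 at 1.30 (adjusted p = 2.84e-06; adjusted p = 0.057 with an estimated correlation). Of 22 G2/M genes, 9 rose and 4 fell (10 and 4 over the list alone), with CDC20 at 2.10, CDK1 at 1.05 and CENPF at -1.59 (adjusted p = 0.000342; adjusted p = 0.0529 with an estimated correlation). UBE2C rose by 0.54 (adjusted p = 0.0279), a call lost without any of the 4 mock libraries (adjusted p = 0.0764 and 0.115 without AI replicates 1 and 2, 0.107 and 0.0797 without AD replicates 1 and 2) and with no filter on low values (adjusted p = 0.0585). Of 14 hypoxia and glycolysis genes, 8 rose and 3 fell, with GAPDH at 1.46, VEGFA at 1.23 and CA9 at 9.29 ± 0.262 RPKM in AD and 4.39 ± 0.156 in AI (adjusted p = 5.26e-05; adjusted p = 0.154 with an estimated correlation, and 0.301 with quantile normalization). Of 20 G1/S genes, 14 fell and 2 rose (15 and 2 over the list alone), with MCM3 at -2.53, CCNE1 at -1.50 and PCNA at -1.45 (adjusted p = 0.0448; adjusted p = 0.188 with an estimated correlation, and 0.232 with TMM scaling).

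Among lists that did not pass after mock transfection, 26 of 48 splicing factors fell and 4 rose, with DDX5 at -3.63 (289.4 ± 19.8 to 23 ± 1.93 RPKM) and SRSF5 at -2.18 (adjusted p = 0.528; 0.00645 with quantile normalization). With TMM scaling the splicing counts were 13 falls and 14 rises, so their direction depended on the scaling. Of 11 PRC2 genes, 8 fell and 1 rose, with RBBP7 at -2.29 and JARID2 at -1.86 (adjusted p = 0.215). With quantile normalization the PRC2 counts were 4 and 3, and with TMM scaling 5 and 2. Of 24 androgen-induced genes, 12 fell and 3 rose (12 and 4 adjusted over the list alone; adjusted p = 0.563), with C1orf116 at -4.53, and with TMM scaling 9 fell and 9 rose. Luminal markers had 4 rises and 7 falls of 14 (adjusted p = 0.994), with the factor FOXA1 at -2.75. Polycomb developmental genes had 0 rises and 7 falls of 8 (adjusted p = 0.0994; 0.0366 with TMM scaling, downward), but 1 and 3 with quantile normalization (adjusted p = 0.0754). Mitochondrially encoded genes had 2 and 7 of 15 (adjusted p = 0.879; 0.00241 with quantile normalization, downward). The H3K27 and H3K36 enzymes had 1 and 7 of 12 (adjusted p = 0.43). PRC1 had 3 and 4 of 17 and EZH2-silenced genes 4 and 4 of 10 (adjusted p = 0.499 each), and mesenchymal markers 1 and 2 of 7 (adjusted p = 0.564). Directions again depended on the scaling: PRC1 had 8 rises and 5 falls with quantile normalization and 7 and 3 with TMM scaling, mesenchymal markers 4 and 1 and 3 and 1.

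In total 7919 of 14227 genes were called after mock transfection, 1731 higher and 6188 lower in AI. The median gene changed by -0.41, against 0.02 after quantile normalization and -0.03 with TMM scaling, and camera compares each list with that shift. After quantile normalization the split was 3440 higher and 3522 lower, and with TMM scaling 3614 higher and 4028 lower.

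The changes in untreated and mock-transfected cells correlated weakly across genes, which are not independent replicates (Pearson 0.148, Spearman 0.105). Of 3148 genes called in both, 515 were higher in AI in both (384 from independent lists) and 1053 lower in both (767 from independent lists), while 1378 went from higher to lower (1374) and 202 from lower to higher (215). Of the 100 largest untreated changes, 74 had the same direction after mock transfection. The AI minus AD changes of the siEZH2 libraries followed those of the mock libraries (Pearson 0.913) and not those of the untreated ones (0.0796). No library is shared by these comparisons.

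**Figure D2:**
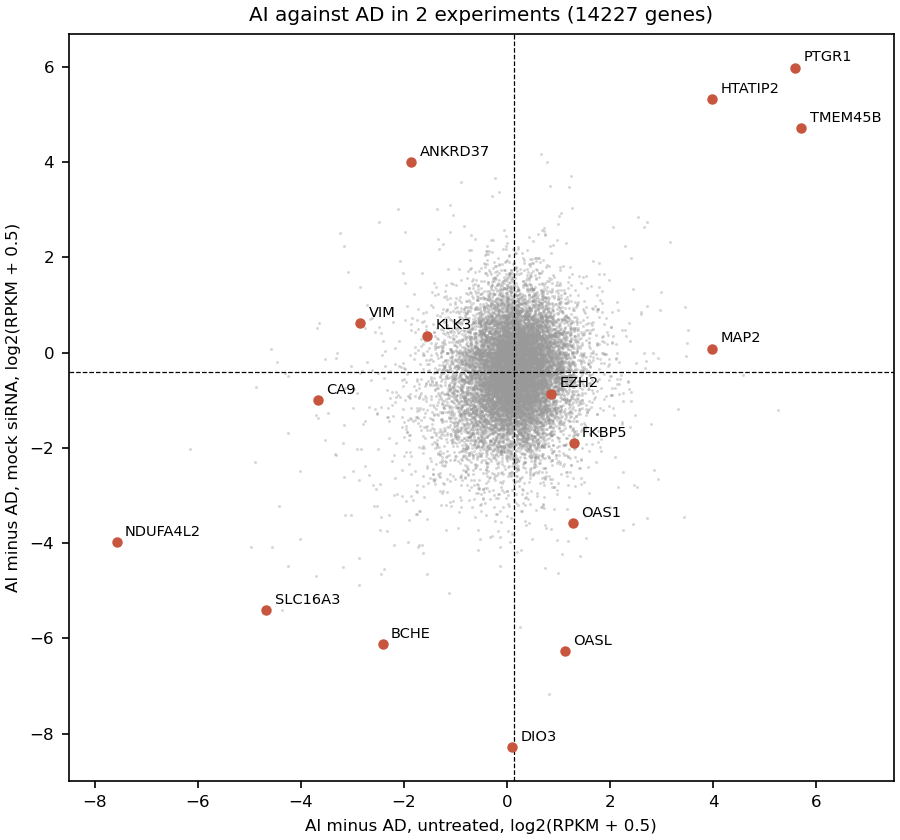
AI minus AD change on the log2(RPKM + 0.5) scale in untreated cells (x axis) and after mock siRNA (y axis) for 14227 genes (grey points); red points are named genes and dashed lines the median gene of each comparison. PTGR1, TMEM45B and HTATIP2 sit high on both axes, while OASL, OAS1 and FKBP5 are positive on the x axis and negative on the y axis.

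**Figure D3:**
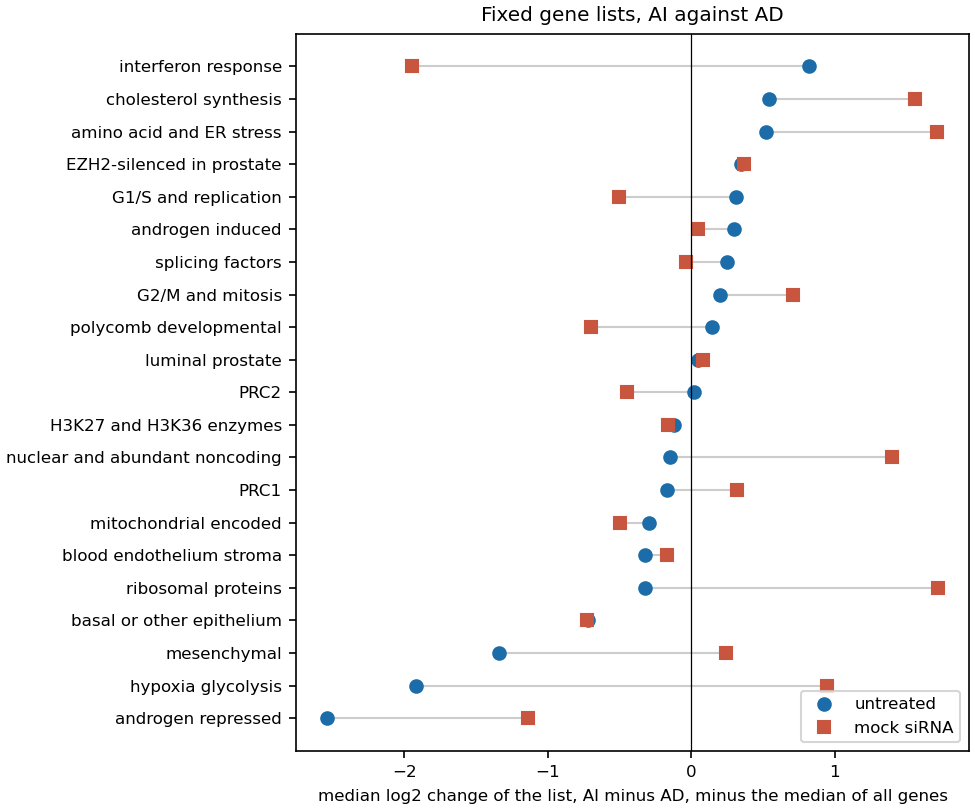
Median AI minus AD log2 change of each gene list minus the median of all genes (x axis), in untreated cells (circles) and after mock siRNA (squares), for the 21 lists with at least 3 tested genes. Hypoxia and glycolysis lies at -1.92 untreated and 0.943 after mock siRNA, and interferon response at 0.818 and -1.95; the mock value of hypoxia and glycolysis did not pass with quantile normalization.

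The transfection experiment asked what siEZH2 changed against mock. In AD cells 2 genes rose and 0 fell among 14227 (limma; 544 at an unadjusted p under 0.05). The named one was MT-TP, a mitochondrial tRNA, listed at 0 in both mock libraries and at 2.01 ± 0.643 RPKM after siEZH2 (adjusted p = 0.0406). Both calls were lost (0 genes) when any of the 4 libraries was left out, with quantile normalization and with TMM scaling. The interferon list (median 0.189, adjusted p = 0.0107) and ribosomal proteins (median 0.103, adjusted p = 0.0107) passed camera upward, but not with an estimated correlation (adjusted p = 0.282 and 0.693).

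In AI cells 208 genes were called after siEZH2, 10 higher and 198 lower, with 2675 at an unadjusted p under 0.05. The named rises were the splicing factor SF3B4 (0.73, from 2.38 ± 0.12 to 4.28 ± 0.658 RPKM, SD, n = 2), the superoxide dismutase SOD3 (0.70) and GRB7 (0.62). The largest falls were PAXBP1 (-1.25), TMEM126B (-1.19), USP16 (-1.09), the spindle checkpoint gene MAD2L1 (-1.08), KLHL1 (-1.08), the exonuclease EXO1 (-1.05) and TTC21B (-1.05); MIR4787, at 4.33 ± 0.474 RPKM after mock and listed at 0 in both siEZH2 libraries, is a microRNA locus and uncertain in poly(A) RNA-seq. Of 22 G2/M genes, 3 fell (7 adjusted over the list alone): TOP2A (-0.92, from 42.3 ± 1.7 to 22.1 ± 1.72 RPKM), CDK1 (-0.84, from 116.6 ± 10.4 to 65.3 ± 12.3 RPKM) and KIF11 (-0.61). RRM1 (-0.64), the noncoding RNA MALAT1 (-1.02) and the PRC2 accessory gene MTF2 (-0.90) fell as well, each the only called member of its list (2 of the G1/S and noncoding lists and 3 of the PRC2 list adjusted over the list alone). Stress genes (median 0.172) and mitochondrially encoded genes (median 0.336) passed camera upward (adjusted p = 0.0284 each), but not with an estimated correlation (adjusted p = 0.389 and 0.69). The count of called genes was 11 with quantile normalization, 28 with TMM scaling, 0 without mitochondrially encoded genes and 0 when any of the 4 AI libraries (siEZH2 replicate 1 or 2, mock replicate 1 or 2) was left out. With a log2 change of at least 1 the count was 25, with no filter 150 and with a pseudocount of 1 it was 173. Other settings called more genes: 305 with a pseudocount of 0.1 and 324 with a mean of at least 2 RPKM. The replicate block gave 371 and a fit of the compared groups alone 1204. Without mitochondrially encoded genes the folds of TOP2A, CDK1 and MALAT1 stayed at -0.92, -0.84 and -1.02. The adjusted p was then 0.102 for TOP2A and CDK1. With unchanged folds, these calls ended through the estimated spread, which draws on all 12 libraries. Leaving out mitochondrially encoded genes rescales each library by their share. That share was 3.79% to 4.06% in transfected AI cells, but 18.01% and 32.06% in the untreated AD replicates. Which libraries widened the spread was not tested. No gene passed for the difference of siEZH2 effects between AI and AD (limma; 976 at an unadjusted p under 0.05), so the larger count in AI is not shown to differ from that in AD. For this difference camera called mitochondrially encoded genes (median 0.559, adjusted p = 0.000122), stress genes (0.177, adjusted p = 0.00285) and cholesterol synthesis (0.0811, adjusted p = 0.0364) upward and G1/S genes (-0.16, adjusted p = 0.0364) downward. With an estimated correlation these calls were lost (adjusted p = 0.563, 0.17, 0.394 and 0.394).

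The RIP libraries asked which RNAs were recovered with EZH2. Ranked by the smallest of the 4 ratios to IgG, the leading transcripts were ACACB, an acetyl-CoA carboxylase (log2 ratios 3.47 and 3.08 in AD, 3.54 and 4.18 in AI), the kinase gene ULK4 (3.09 in AD replicate 2, 3.86 and 2.73 in AI, and listed at 0 in AD IgG replicate 1) and BTAF1 (3.15, 2.83, 2.63 and 3.48). Higher in IgG were the nuclear RNA 7SK (-2.06, -1.94, -2.56 and -4.92), MT-RNR1, a mitochondrial ribosomal RNA (-2.33, -1.67, -2.33 and -3.21) and MALAT1 (-2.18, -1.39, -1.56 and -1.98). These genes were chosen after their values were seen, since no gene passed the main test. In AI replicate 2 the ratios of ACACB, ULK4 and BTAF1 rest on few IgG reads. That IgG library listed them at 1.3, 2.43 and 5.07 RPKM, where 1 read in a gene of 1 kb is worth 12.3 RPKM. It listed only 6960 genes above 0, and the other ratios in it depend on the pseudocount. EZH2 RNA itself stood at 19.7 ± 5 RPKM in EZH2 RIP and 7.47 ± 4.34 in IgG of AD cells (log2 change 1.44, adjusted p = 0.66), and at 17.7 ± 2.98 and 1.87 ± 2.64 in AI cells (3.64, adjusted p = 0.109). The AI ratio depends on the pseudocount, because IgG replicate 2 of AI, with 0.0814 M reads, listed EZH2 at 0. EZH2 passed without AI IgG replicate 1 (5.18, adjusted p = 0.0231), where that library alone stood for IgG. This fold is set by the pseudocount. With the replicate number as a block EZH2 RNA passed in AI, as given with the alternatives below, though no label says that the numbers pair libraries.

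By list, mitochondrially encoded genes lay lowest against all genes, with medians of -3.03 and -1.56 in AD and -2.78 and -3.45 in AI (15 genes). Ribosomal protein genes also lay below all genes in each, at -2.75, -0.552, -1.71 and -1.46 (34 genes), as did noncoding RNAs (-0.233, -1.17, -1.55 and -1.13), luminal markers (-1.21, -0.34, -0.901 and -1.26), androgen-induced genes (-0.822, -0.493, -0.871 and -1.14) and hypoxia genes (-1.79, -0.393, -0.685 and -0.7). G2/M genes lay above all genes in each, at 0.546, 0.409, 0.258 and 0.446 (22 genes), as did PRC2 genes (0.291, 0.654, 0.712 and 0.048) and interferon genes (0.771, 0.683, 0.77 and 0.127), but none of these 3 lists passed camera, with adjusted p = 0.269 for G2/M in AD and 0.336 in AI. Meanwhile splicing factors scattered around 0 (-0.004, 0.263, 0.115 and -0.418; 47 genes). Camera called 8 of 19 lists in AD and 5 in AI at the preset correlation and 0 in either with an estimated correlation. The H3K27 and H3K36 enzymes were the only list called upward, in AD (0.517 and 0.823, with 0.571 and -0.409 in AI; 12 genes). Their adjusted p was 0.000875, but adjusted p = 0.11 with quantile normalization and 0.47 with an estimated correlation. Mitochondrially encoded genes had adjusted p = 8.28e-15 in AD and 6.92e-20 in AI, and adjusted p = 0.293 and 0.354 with an estimated correlation.

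Single genes did not pass in the main model, which has no replicate block. There limma called 0 of 13667 genes in AD (1383 at an unadjusted p under 0.05), 0 in AI (2930) and 0 for the difference between AI and AD (436). Without the block, voom on the recovered reads also called 0, 0 and 0, with all genes as with the 9678 under a mean of 5 RPKM. Without IgG replicate 1 of AI the count for AI was 733. All 4 ratios were above 0 for 4780 genes and below 0 for 731, an imbalance that goes with medians of all genes above 0 (0.678 and 0.192 in AD, 0.581 and 1.16 in AI). After quantile normalization the median change was -0.04 in AD and -0.06 in AI. The ratios of the replicate numbers correlated across genes at 0.431 in AD and 0.259 in AI. The labels name a pair of sequencers for RIP without tying libraries to them, so an effect of the sequencer could not be tested. Deviations of replicates with equal numbers correlated between RIP groups at 0.0972 to 0.713, though no label says that the numbers pair libraries. With the replicate number as a block, limma called 483 genes in AD and 1338 in AI.

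**Figure D4:**
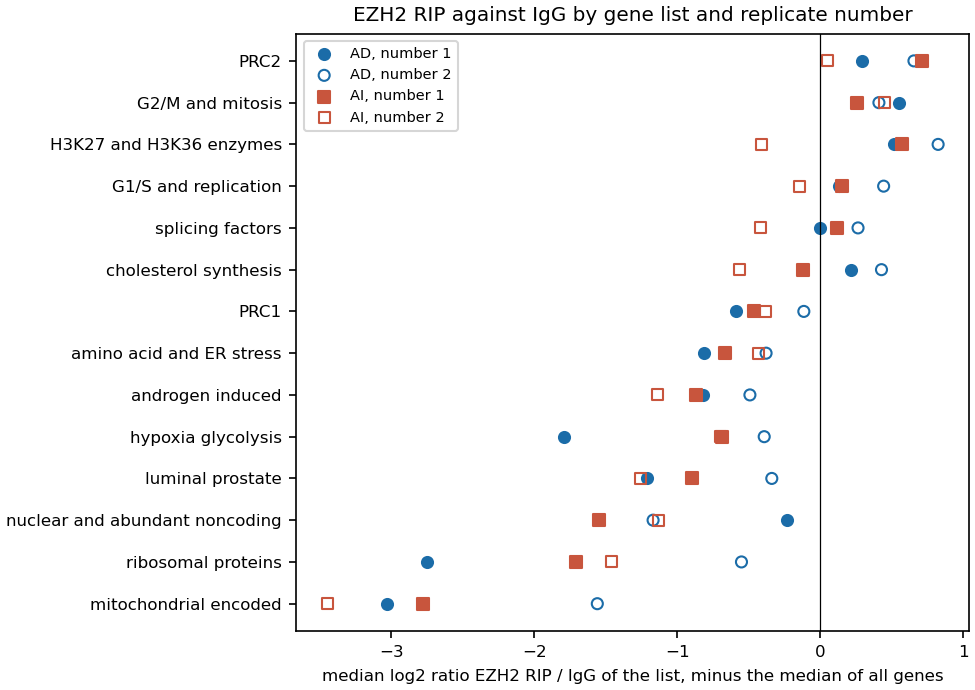
Median log2 ratio of EZH2 RIP to IgG of each gene list minus the median of all genes (x axis), for lists with at least 10 genes; circles are AD and squares AI, filled symbols replicate number 1 and open symbols replicate number 2. Mitochondrially encoded genes lie between -1.56 and -3.45 and G2/M genes between 0.258 and 0.546.

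H3K27me3 lists asked where the mark differs between AD and AI. The widest regions marked in both AD lists and in neither AI list (GRCh38) were chromosome 17 from 74643840 to 74660579, which overlaps no gene of the table and lies 10552 bp from RAB37, chromosome 22 from 49320482 to 49336045, 437233 bp from the nearest coding gene BRD1, and chromosome 17 from 51649765 to 51664085, inside CA10. The widest marked in both AI lists and in neither AD list were chromosome 19 from 1744602 to 1769043, over the start of the span of the homeobox gene ONECUT3, chromosome 19 from 33521698 to 33541668, at the edge of PEPD, and chromosome 10 from 131235702 to 131254300, inside TCERG1L. Of 118.5 Mb marked in both AD lists, 30.3 Mb (25.6%) were in neither AI list, and of 151.5 Mb marked in both AI lists, 46.1 Mb (30.4%) were in neither AD list. The lists held 124079 and 72749 peaks over 229.6 and 184.4 Mb in AD, and 70791 and 71572 peaks over 228.5 and 213.6 Mb in AI. The Jaccard index was 0.401 within AD and 0.521 within AI, against 0.3 to 0.364 between them (mean 0.332). With 2 lists a group no permutation test can pass, and the gap to the AD pair is small.

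EZH2 lists shared little. They held 53911 and 12399 peaks in AD and 11933 in AI, and the Jaccard index was 0.0137 within AD and 0.00589 and 0.009 between AD and AI. EZH2 peaks lay on H3K27me3 peaks of the same cells more often than shuffled peaks did: between 16.4% and 20.9% in AD, against shuffled means of 8.38% to 10.7%, and 15.0% and 14.3% in AI, against 9.38% and 8.79%. In none of the 6 pairs of lists did any of 1000 shuffles reach the observed share. The shuffles placed peaks anywhere along a chromosome, including stretches where no peak can be called. They matched neither gene density nor copy number. The chance level may therefore be too low, and the shares do not show that EZH2 and the mark occupy the same sites for a biological reason. The shuffles describe pairs of lists, not the conditions, and AI had a single EZH2 list.

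**Figure D5:**
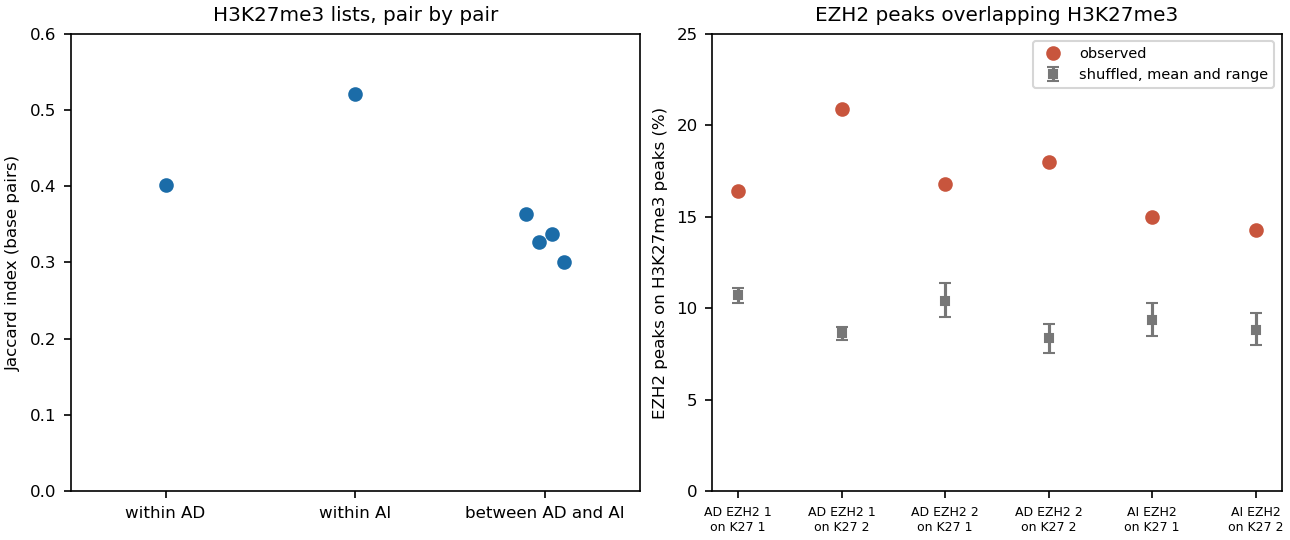
Left, Jaccard index in base pairs (y axis) of each pair of H3K27me3 lists, within AD, within AI and between them. Right, percent of EZH2 peaks that overlap H3K27me3 peaks of the same cells (red points), with the mean and the full range of 1000 shuffles (grey squares and bars); observed shares lie at 14.3% to 20.9% and shuffled means at 8.38% to 10.7%.

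Expression was set beside the mark over gene spans. Among 51 genes that lost H3K27me3 in AI, MAP2 (chromosome 2, 209424047 to 209734112) rose from 0.155 ± 0.0778 to 9.88 ± 1.96 RPKM (SD, n = 2; log2 change 3.98) in untreated cells, the glutamate receptor gene GRIN3A rose by 3.49, CD177 by 2.12 and C8orf48 by 2.07, while the trefoil factor TFF1 fell by 3.30. Among 309 genes that gained it, AZGP1, a secreted zinc-binding glycoprotein, fell from 162 and 146 RPKM to 15.7 and 14.1 RPKM in the single libraries (log2 change -3.33), KCNK1 fell by 3.33, SCD5 by 2.99 and SLITRK3 by 2.19, while ATP2B1 rose by 2.40. Several of these did not follow after mock transfection: MAP2 was at 0.08 (adjusted p = 0.728), GRIN3A at 0.20, TFF1 at -0.01 and KCNK1 at -0.12, none of which passed, while CD177 fell by 0.66, C8orf48 by 1.30 and ATP2B1 by 1.02. In untreated cells 18 lost genes rose and 4 fell, 77 gained genes rose and 44 fell, 138 of 609 kept genes rose and 88 fell, and 2548 of 10403 unmarked genes rose and 1212 fell. After mock transfection, where most called genes were lower in AI, 8 lost genes rose and 21 fell, 34 gained genes rose and 146 fell, 63 kept genes rose and 309 fell, and 1420 unmarked genes rose and 4487 fell. The mean change of lost genes in untreated cells was 0.336 above that of the 609 genes that kept the mark (permutation test, p = 0.00745, adjusted p = 0.0159). The share of genes higher in AI was 64.7% for lost, 62.1% for gained, 62.4% for unmarked and 57.3% for kept genes. By this share, lost genes stood close to gained and unmarked ones when untreated. After mock transfection the shares were 45.1%, 25.6%, 32.4% and 26.6%. Gained genes did not differ from kept ones (-0.00328, permutation p = 0.954), and 10403 genes without the mark lay 0.0554 above kept ones (p = 0.0473, adjusted p = 0.0709). After mock transfection lost genes lay 0.382 above kept ones (permutation p = 0.00797, adjusted p = 0.0159), gained genes 0.0709 (p = 0.302) and unmarked genes 0.23 above (p = 1e-05, the smallest the resamples can give; adjusted p = 6e-05). With at least 10% of the span required to be covered, the untreated difference of lost genes was 0.217 (permutation p = 0.442). Many of the named genes fall short of that coverage. AD peaks covered 7.09% and 4.65% of the MAP2 span with its flanks, 6.18% and 5.15% of GRIN3A and 6.25% and 3.3% of CD177. AI peaks covered 3.09% and 4.53% of KCNK1 and 4.39% and 1.54% of SCD5, and under 10% of AZGP1 and ATP2B1. Coverage was larger for TFF1 (39.9% and 68.9%), C8orf48 (47.3% and 27.6%) and SLITRK3 (46.9% and 42.6%).

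The last question was whether genes with EZH2 peaks over their span, or transcripts recovered in EZH2 RIP, moved after siEZH2. Genes with EZH2 peaks over the span lay 0.0264 above genes with neither EZH2 nor H3K27me3 peaks in AD (2794 against 5165 genes) and 0.0548 above in AI (3009 against 8429), with p = 1e-05 in both, the smallest 100000 permutation resamples can give (adjusted p = 2e-05). These classes were not matched on gene length or expression. Only 2.66% of the EZH2 peaks of AD replicate 1 overlapped replicate 2, so a span with peaks in both lists need not hold a shared one. The AD shift appeared without detectably lower EZH2, so it cannot be read as a response of genes bound by EZH2. In AI a knockdown was neither shown nor excluded, and the AI and AD shifts were not tested against each other. The AI shift therefore does not show such a response and does not exclude it. H3K27me3 genes did not differ in AD (-0.00159, permutation p = 0.866) or AI (-0.00841, permutation p = 0.418). The 500 transcripts with the largest RIP enrichment lay 0.0237 above matched others in AD (permutation p = 0.0216, adjusted p = 0.0432) and 0.00648 above in AI (p = 0.66). Without matching the AD value was 0.0119 (permutation p = 0.233), and over the alternatives tried neither the size nor the sign of the RIP shifts was stable in AD or AI. The siEZH2 libraries of AD showed no lower EZH2.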

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

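The tests of scaling, mitochondrial reads, swapped labels, the state or source of the cells, and the contrast between experiments itself were chosen only after the result was seen. EZH2 was 0.86 higher on the log2 scale in AI than in AD when untreated and 0.86 lower after mock transfection, a difference of -1.72 (SE 0.259, limma adjusted p = 0.000513). FKBP5 differed by -3.19 (adjusted p = 3.45e-06), higher in AI when untreated and lower in AI after mock transfection. KLK3 differed by 1.9 (adjusted p = 0.000298), TMPRSS2 by -1.04 (adjusted p = 0.000668), CDC20 by 1.93 (adjusted p = 4.1e-05) and UBE2C by 0.86 (adjusted p = 0.0185). CDK1 did not pass (difference -0.08, adjusted p = 0.784). In total 7139 of 14227 genes differed between the experiments, 1279 upward and 5860 downward, with a median difference of -0.545. That downward majority depended on the scaling: quantile normalization gave 2620 and 2902 with a median of 0.0094, and TMM scaling 2945 and 3112 with a median of -0.0268.

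Among gene lists, hypoxia and glycolysis genes had a median difference of 2.61, with 14 of 14 members higher after mock transfection than when untreated in the AI minus AD contrast. Interferon genes had a median of -2.7, with 12 of 12 lower. Cholesterol synthesis genes lay at 0.692 (10 higher, 2 lower), stress genes at 0.669 (7 and 4) and mesenchymal markers at 0.801 (4 and 1). These 5 lists also passed with an estimated correlation (adjusted p = 0.0279 for the first 4 named and 0.0399 for mesenchymal markers). The G1/S list lay at -1.13 (1 higher, 16 lower), noncoding RNAs at 1.21 (7 and 2), ribosomal proteins at 1.51 (27 and 0), splicing factors at -0.737 (1 and 25) and PRC1 genes at 0.00683 (5 and 3), which is above the median of all genes. With an estimated correlation these calls were lost (adjusted p = 0.0571, 0.0513, 0.128, 0.128 and 0.228), and splicing factors also did not pass with TMM scaling (adjusted p = 0.28).

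The difference between the experiments was weighed against technical sources. Scaling cannot be the whole source, since 57.0% of the 7139 genes were still called after quantile normalization, and neither can mitochondrial reads, since 88.8% were still called without mitochondrially encoded genes. A swap of AD and AI labels in the transfected libraries would reverse the largest untreated changes, whereas 74 of the 100 largest kept their direction. A different state or source of the cells cannot be told apart from the response to transfection and from handling, because no library is shared by the experiments, and it may underlie part of the 7139 genes. A difference in how AD and AI cells respond to transfection stays open as an untested biological explanation.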

How the results depend on the processing

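The tests without mitochondrially encoded genes, with voom on all genes or on those under a mean of 5 RPKM, with 10% or more of a gene span covered, and with RIP transcripts called with the replicate block were chosen only after the result was seen. For untreated AI against AD (4922 genes) the count was 1758 in a fit of these groups alone and 1621 at a log2 change of at least 1, and 3648 to 4775 on leaving out 1 library. After mock transfection (7919) it was 4137 at a log2 change of at least 1 and 6466 to 6583 on leaving out 1 library. Across lists and planned comparisons camera made 36 calls at the preset correlation and 4 with an estimated one. VWF after mock transfection went from -0.58 to 0.0168 with quantile normalization and ENO2 from -0.38 to 0.102 with TMM scaling.

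For siEZH2 in AD (2 genes) the count was 1 with a pseudocount of 0.1 or a mean of at least 2 RPKM, and 45 with no filter. It was 0 with a pseudocount of 1, quantile normalization, TMM scaling, the replicate block, these groups alone or no mitochondrially encoded genes, and 0 on leaving out any library. For siEZH2 in AI (208 genes) it was 324 with a mean of at least 2 RPKM, 11 with quantile normalization, 28 with TMM scaling, 371 with the replicate block, 1204 in these groups alone, 25 at a log2 change of at least 1, and 0 without mitochondrially encoded genes or on leaving out any library. For the difference of siEZH2 effects (0 genes by limma, 976 at an unadjusted p under 0.05) it was 1 with a pseudocount of 0.1, 38 with no filter and 1 in these groups alone.

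The replicate numbers are not stated to pair libraries. The deviations of replicates from their group mean correlated between groups at -0.00442 to 0.13 in RNA-seq, except 0.701 for untreated AD and AI, and at 0.0972 to 0.713 in RIP, so the replicate block was kept as an alternative only. With it RIP gave 483 genes in AD and 1338 in AI in place of 0 (limma; 1383 and 2930 at an unadjusted p under 0.05), and voom with the block 2302 and 2699. In genes under a mean of 5 RPKM, whose lengths simulation recovered, voom with the block gave 244 and 653. EZH2 RNA, which lay above that mean, passed in AI with the block (3.64, adjusted p = 0.0239) and with voom and the block (2.46, adjusted p = 0.00267; AD 1.58, adjusted p = 0.00199). With the block camera called 8 lists in AI in place of 5, PRC2 among them (adjusted p = 0.0438). Leaving out 1 library gave 0 to 733 in AI, where 733 needed the loss of IgG replicate 1.

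The higher-scoring part of each list gave a Jaccard index of 0.292 for H3K27me3 between AD and AI (0.332), and 14.5% (AD) and 11.1% (AI) of EZH2 peaks on H3K27me3 (18.1% and 14.7%). Overlap over most of a peak gave 45.2% shared H3K27me3 peaks (54.1%) and 13.9% of AI EZH2 peaks on H3K27me3. For genes that lost H3K27me3 the difference of 0.336 became 0.217 with at least 10% of the span covered. The siEZH2 shift of RIP-enriched transcripts in AD (0.0237) was 0.0119 unmatched, 0.00586 with a pseudocount of 1 and -0.0214 (permutation p = 0.0265) for transcripts called with the replicate block, and in AI (0.00648) it was -0.0295 (permutation p = 0.0025) for the latter. For these changes the cause was not tested, except that the log2 limit, higher scores and wider overlap narrow what is counted.

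Of the summary values above and the others reported, 131 stayed within 1.5 times a count, within the spread of samples or on the same side of the threshold, 44 moved, 3 weakened and 2 reversed. The 131 include RIP counts that stayed at 0 in a design that recovered 0% of simulated changes, and counts whose split turned, as for untreated AI against AD (3158 higher and 1764 lower, but 2080 and 2416 with TMM scaling). Of the named genes, 326 of their values were unchanged in call with quantile normalization and 29 lost it, against 331 and 23 with TMM scaling and 296 and 31 in the compared groups alone. A library left alone in its group is assumed to vary like the other groups. edgeR and DESeq2 (no counts at hand) and promoter windows of other widths (no start sites at hand) were not run. The shallow IgG libraries, down to 0.0814 M reads, limit the RIP ratios.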

Other observations

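The tests of mock against untreated cells and of chance for chromosome 9 were chosen only after the result was seen. In AD cells interferon genes were higher after mock transfection than in untreated cells, as were LCN2 and CCL2: LCN2 went from 0.14 ± 0.198 to 115.8 ± 1.29 RPKM (SD, n = 2), the interferon-induced OASL from 0.01 ± 0.0141 to 61.4 ± 4.4 and OAS1 from 0.14 to 8.05 ± 0.608, and CCL2, a chemokine gene, from a listed 0 to 14.6 ± 1.22. Of 12 interferon genes, 12 rose (limma; camera adjusted p = 9.51e-07, and adjusted p = 0.0302 with an estimated correlation). The androgen target FKBP5 rose as well, by 2.08 on the log2 scale. In total 6455 genes were called in AD, 5355 higher and 1100 lower, and after quantile normalization 2634 higher and 2483 lower.

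In AI cells hypoxia genes and part of the stress genes were higher after mock transfection than in untreated cells. ANKRD37 of the hypoxia list went from 6.73 ± 0.0636 to 904.9 ± 47.5 RPKM (SD, n = 2) and the stress factor ATF3 from 33.3 ± 0.651 to 967 ± 5.44. NDRG1, a member of the androgen-induced list, went from 13.2 ± 0.269 to 526.2 ± 9.74, and BHLHE40, which is in none of the lists, from 4.47 ± 0.304 to 235.4 ± 4.18. Of 14 hypoxia and glycolysis genes, 14 rose (camera adjusted p = 1.31e-12, but adjusted p = 0.0716 with an estimated correlation). Of 15 stress genes, 9 rose and 2 fell (adjusted p = 0.00147, also 0.0716 with an estimated correlation). The RNA helicase gene DDX5 fell by 3.87. Mitochondrially encoded genes fell in 15 of 15 members in both cell types, with medians of -4.23 in AD and -5.04 in AI (camera adjusted p = 2.28e-23 and 5.81e-08, but adjusted p = 0.0962 and 0.335 with an estimated correlation). In total 8121 genes were called in AI, 3064 higher and 5057 lower, and after quantile normalization 3727 higher and 3810 lower. Without mitochondrially encoded genes the counts were 1930 and 6665, and the median gene changed by -0.509, so the split depended on the share of those genes. Untreated and transfected libraries are treated here as separate experiments, which the labels do not state. They have no library in common, so the effect of transfection and that of the experiment cannot be separated.

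Genes of chromosome 9, the chromosome of PTGR1, were higher in AI. Their 574 tested genes had a median of 0.325 above all genes when untreated, 0.264 after mock transfection and 0.259 after siEZH2. A chance draw was tested with 10000 random sets matched on expression, and the lower percentile of chromosome 9 was 100.0. More copies of chromosome 9 in AI would lift windows along it, and 0 of its 6 windows of 20 Mb lay at or below the median of all genes. Chromosome 9 had the highest median of all chromosomes in both comparisons, however. Windows above the median in the same data were thus partly fixed by that choice, so they cannot decide whether more copies are the source. However, 23 chromosomes were looked at, and 11 lay outside the central 95% in both comparisons. Of these 6 lay above, chromosomes 2, 6 and 13 among them, and chromosome 22 also had all 3 windows above the median. Chromosome 9 held 1.88% and 2.16% of the EZH2 peak base pairs in AD and 4.79% in the single AI list. Chromosome 2 held 2.65% and 2.75% in AD and 4.36% in AI, and chromosome 22 held 1.3%, 0.914% and 2.45%. A larger EZH2 share in AI was thus not particular to chromosome 9. For H3K27me3 chromosome 9 held 2.31% and 2.35% in AD and 3.53% and 3.64% in AI. Peak shares do not measure copy number. Neighbouring genes are not independent, and DNA copy number and GC content were not tested.

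Several leading transcripts of the EZH2 RIP, such as HERC2 and VPS13B, belong to very long genes, so the ratio was compared with the transcript lengths recovered from the RPKM steps. Over all 13624 genes the rank correlation was -0.096 and 0.143 in AD and -0.0779 and -0.183 in AI, against -0.233, -0.0804, -0.213 and -0.246 when each EZH2 library was thinned to the depth of its IgG library. Lengths of abundant genes came out too short, however, and in the 9678 genes under a mean of 5 RPKM the gap was smaller, with -0.19 and 0.0665 in AD and -0.18 and -0.207 in AI, against -0.246, -0.055, -0.226 and -0.221 in thinned libraries. Unequal depth lowered long transcripts in all 4 thinned libraries (by -0.562 times the observed correlation in AD replicate 2 over all genes), which argues against it as the source of an excess of long transcripts, though it may account for the negative values. Few IgG reads may matter and could not be settled. Among genes with at least 20 expected IgG reads the correlation was 0.0844 in the deepest IgG library (AD replicate 2, 5017 genes), 0.394 in AD replicate 1 (462 genes) and 0.257 in AI replicate 1 (1106 genes), against 0.00439, -0.0179 and 0.027 in thinned libraries. The larger values favour an excess of long transcripts, but many of these genes are abundant and without a dependable length. Under a mean of 5 RPKM the correlation was 0.0217 in AD replicate 2 (2149 genes) and -0.0267 in AI replicate 1 (75 genes), and AD replicate 1 held only 14 such genes. Whether long transcripts are in excess is left open, and no biological explanation was tested.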
